A study of Mus musculus with 7 samples.

How the data were processed

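The series holds 7 RNA-seq libraries of OT1 CD8 T cells sorted from mouse tumours, 4 from tumours without and 3 from tumours with SMARTA CD4 T cells. Per the labels' protocols, cells were sorted into Trizol, 6-15 ng of total RNA were amplified over 12 cycles with the SMART-seq V4 kit, which starts from polyadenylated RNA and does not mark strand, and libraries were read as 50 base pairs from both ends on an Illumina HiSeq instrument. Per the submitters' processing notes, STAR 2.6.0c, featureCounts 1.6.2 and the genome build GRCm38.p6 were used. Per the file headers, the authors counted read pairs per gene name over the exons of GENCODE M17 with featureCounts, without strand and with the default treatment of reads that match several places or several genes, which leaves them out. The deposited values are therefore raw counts, not normalized, with 53656 gene rows in each file. Near-identical family members (Ifit3 and Ifit3b, Bcl2a1b and Bcl2a1d, Ly6c1 and Ly6c2, Klra genes, granzymes of 1 cluster, globins, T cell receptor segments) and overlapping or antisense genes are uncertain under this counting.

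Samples were grouped by their titles. Counts were read with R 4.3.3 and tested with edgeR 4.0.16: genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, libraries were scaled with TMM, and the 2 groups were compared with all 7 libraries in a robust quasi-likelihood fit (glmQLFit and glmQLFTest, two-sided) with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are with minus without SMARTA, and their standard errors were derived from the fold change and its F value. CPM are TMM-scaled for single genes and per plain library total for summed lists; log2 CPM used a prior count of 2. The common dispersion was 0.28, a coefficient of variation between libraries of 0.529.

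The lists were 26 programme lists and 12 marker lists, 823 entries in all, written with the tests, the alternatives and the naming rule before the data were examined. A list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 38 lists; camera with an estimated correlation and fry were alternatives. With the estimated correlation none of the 18 lists called by camera passed; by fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes, 13 passed. The members called were also counted with the adjustment over the list alone. Summed CPM of marker lists were compared with a two-sided exact permutation test over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0286.

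The text names genes by a fixed rule: the 12 largest increases and 12 largest decreases among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, without gene models lacking an established symbol or immunoglobulin and T cell receptor segments; up to 4 called members of each list, or the 2 with the smallest p where none was called; and 20 genes fixed in advance. Nr4a2, Cd200 and Ltb4r1 are named outside the rule, after their values were seen, to complete a count. Also outside it, and chosen after the data were seen, are the largest genes of marker sums, the gene families and the T cell receptor segments.

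The fits were tested on simulated counts for the same 15896 genes with the spread of these libraries and 200 changed genes. For the comparison with against without SMARTA, edgeR recovered 41% of 4-fold and 3% of 2-fold changes with 1 false call, limma-voom 37% and 2% with 2 false calls, and DESeq2 61% and 21% with 43 false calls. A changed gene is therefore often missed here, and the absence of a call is not evidence of no change. With a small simulated spread 97% were recovered, with 10 false calls. Of 38 simulated lists the 2 that were shifted were called and none of the 36 others. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists falsely whose genes vary together. The estimated correlation was 0.451 in the interferon-stimulated and 0.735 in the mitosis list.

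The alternatives were relative log expression and upper-quartile scaling, no filter, a filter of CPM of at least 5 in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit without robust estimation, an adjusted p under 0.01, a log2 fold change of at least 1, the replicate number as a block, and each library left out. Chosen after seeing the data were the number in the file name as a block, the marker sums without their largest gene, library totals alone, both libraries that stand apart left out, and removal of trends with GC content and gene length, fitted with mgcv 1.9.3 over the 99.8% of tested genes with a GC value. No library was left out of the main results. Within each group the counts of every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 97.2 to 461 over genes with at least 20 reads in the pair), so none was counted as a copy. Figures were drawn with matplotlib 3.10.9.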

Results

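The series measured messenger RNA in OT1 cells, CD8 T cells that carry a transgenic receptor for an ovalbumin peptide. The cells were sorted by CD8 and the congenic marker CD45.1 from B16-OVA-GP61 tumours, grown from a mouse melanoma line that expresses ovalbumin and the GP61 epitope of a virus glycoprotein. In 4 libraries the tumours came from mice without SMARTA cells, and in 3 libraries SMARTA cells were present; these are CD4 T cells with a transgenic receptor for GP61. The title of the series asks what part CD4 T cells have in the reprogramming of tumour-specific CD8 T cells, and the comparison of the 2 groups addresses this at the level of transcripts. Libraries held 47382620, 41341343, 48572380 and 46310426 counts without SMARTA and 49438357, 42680170 and 38092722 with SMARTA, in replicate order. Between 19728 and 22352 genes had at least 1 count. At these depths a gene with no count in a library lay below 0.0607 to 0.0788 CPM (counts scaled to library size), the level of 3 counts, a floor that covers counting error only. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

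OT1 cells from tumours with SMARTA cells carried more transcript of interferon-stimulated genes, of the adhesion genes Itgae and Cdh1 and of several chemotactic receptors. They carried less transcript of the exhaustion-associated factor Tox, of the chemokines Ccl3, Ccl4 and Xcl1 and of genes of DNA replication and mitosis. Ifit1, an RNA-binding protein induced by interferon, was 15.7-fold higher with SMARTA (27.0 ± 11.4 CPM without against 423 ± 328 CPM with, mean ± SD, n = 4 and 3), and Tox was 8.49-fold lower (217 ± 107 against 25.5 ± 2.73 CPM). Of the 15896 genes tested, 500 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 241 higher and 259 lower with SMARTA, and 449 of them differed by at least 2-fold. All 500 had no overlap between the libraries of the groups; over all genes tested 19.2% had none, against 5.71% expected by chance.

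The count of calls depended on which libraries entered. It was 65, 398, 98 and 17 with replicate 1, 2, 3 or 4 without SMARTA left out, and 907, 37 and 53 with replicate 1, 2 or 3 with SMARTA left out. In each of these fits every one of the 500 genes that was tested kept its direction. Of the 75 called genes that the naming rule covers, 28, 62, 37 and 9 stayed called with replicate 1, 2, 3 or 4 without SMARTA left out and 69, 12 and 20 with replicate 1, 2 or 3 with SMARTA left out. Of these genes 8 stayed called in all 7 fits and 3 in none. With library totals in place of TMM factors 29.1% of 561 calls were higher, against 48.2% of the 500, and the median log2 fold change of all genes moved to −0.16, so that changes of this size depend on the scaling.

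The largest increases among called genes of moderate or high expression were mostly interferon-stimulated genes: Mx2 (log2 fold change 4.05), Ifit3b (4.03), Ifit1 (3.97), Oasl2 (3.61), Ifit3 (3.47), Rsad2 (3.35) and Ifi204 (3.31). The others were Cdh1 (3.65), Dtx4 (3.64), B4galnt4 (3.26), Treml2 (3.25) and Itgae (3.17). The largest decreases were those of Serpinb9b, a member of the granzyme inhibitor family (−7.56), neurogranin, Nrgn (−5.99), the glutamate transporter Slc17a6 (−5.75), Slc9b2 (−5.38), and proenkephalin, Penk (−4.93). They were followed by Ccl9 (−4.33), the protease inhibitor Serpine2 (−4.29), Synpo (−4.29), osteopontin, Spp1 (−4.18), Zbtb32 (−4.11), Ccl3 (−3.92) and Ccl1 (−3.84). Nrgn, on chromosome 9 from 37544492 to 37552904 (GRCm38), fell from 149.7 ± 73.5 to 2.34 ± 1.05 CPM (edgeR adjusted p = 0.00957). Penk, on chromosome 4 from 4133531 to 4138819, fell from 35.5 ± 7.85 to 1.15 ± 0.488 CPM (edgeR adjusted p = 0.00626). Of these 24 genes, Cdh1, Itgae, Nrgn and Penk were called in all 7 fits that leave out 1 library, while Treml2 and Serpine2 were called in none of them, with log2 fold changes from 2.73 to 3.61 and from −4.78 to −3.25. Serpinb9b, Slc17a6 and Slc9b2 were called in 3, 2 and 2 of the 7 fits, and reached −8.92, −7.03 and −6.91 in those without replicates 2, 3 and 2 with SMARTA, which did not call them. The other 15 genes were called in 1 to 6 of the 7.

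**Figure D1:**
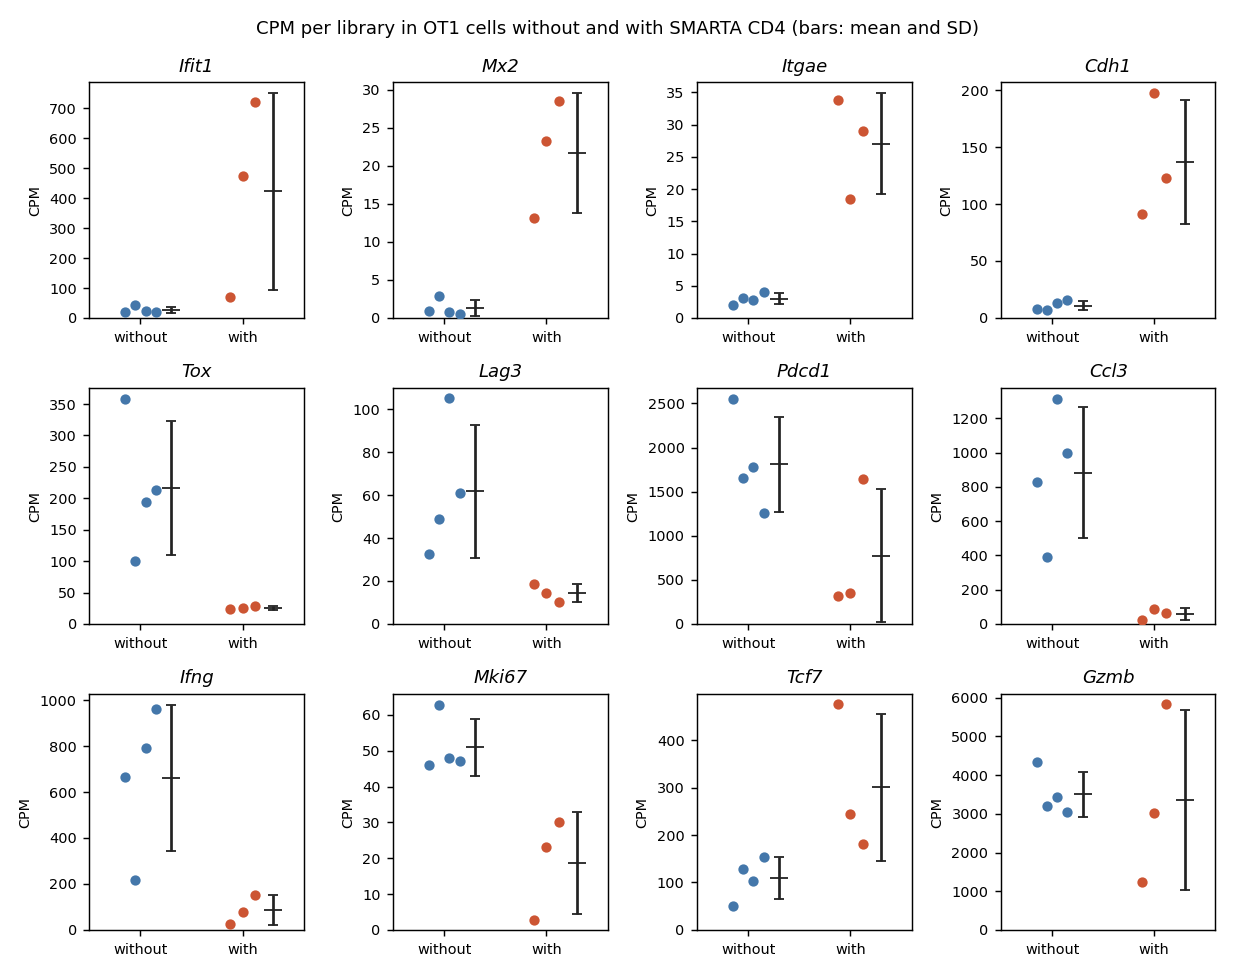
CPM (TMM-scaled, linear axes from 0) of 12 genes in each library without (blue, n = 4) and with SMARTA (orange, n = 3), points in replicate order, with mean and SD as black bars. Ifit1, Mx2, Itgae, Cdh1, Tox, Lag3 and Ccl3 were called by edgeR and do not overlap between the groups; Pdcd1, Ifng, Mki67, Tcf7 and Gzmb were not called, and Pdcd1 and Gzmb overlap.

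Type I interferon-stimulated genes rose as a group with SMARTA: 23 of 30 tested members were called higher and none lower, 29 when adjusted over the list alone, and all 30 had a positive log2 fold change, with a median of 2.13. Isg15, a ubiquitin-like modifier, rose from 24.3 ± 3.26 to 110.3 ± 22.9 CPM (log2 fold change 2.18 ± 0.22, SE; edgeR adjusted p = 0.00957). Irf7, a transcription factor of the interferon response, rose from 159 ± 9.49 to 595 ± 105 CPM (1.90 ± 0.17; edgeR adjusted p = 0.0082), and Oas3 and Oasl1 rose by 2.08 and 2.81 log2 units. The summed CPM of the list was 2053 ± 46.1 without and 6330 ± 1999 with SMARTA, where replicates 1, 2 and 3 had 4108, 6902 and 7981. The list differed from other genes by camera (adjusted p = 1.35e-51), and adjusted p = 0.104 with an estimated correlation. The number of members called was 7, 18, 12 and 5 with replicates 1, 2, 3 and 4 lacking SMARTA left out in turn. It was 27, 5 and 7 with replicates 1, 2 and 3 with SMARTA left out, and replicate 1 holds the erythroid transcripts described with the markers.

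Genes of the interferon gamma response and of antigen presentation were higher with SMARTA in all 27 tested members, with a median log2 fold change of 0.70, but only 2 were called, and 9 when adjusted over the list alone. The interferon gamma receptor chain Ifngr1 rose by 1.23 ± 0.18 (SE; 1465 ± 227 to 3444 ± 417 CPM) and the GTPase Irgm1 by 1.40 ± 0.25 (256 ± 49.8 to 674 ± 205 CPM). By camera the list was higher (adjusted p = 7.31e-09), with adjusted p = 0.17 with an estimated correlation. Without replicate 1 with SMARTA 12 members were called, and with any of the others left out at most 1.

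Among inhibitory receptors and exhaustion-associated genes 7 of 24 tested members fell with SMARTA and none rose; adjusted over the list alone, 8 fell and 1 rose. Those that fell were Tox, a transcription factor of exhausted T cells, and the receptors Cd160, Cd244 and Lag3. The others were Cd200, which encodes a membrane ligand, the G protein regulator Rgs16 and the nuclear receptor Nr4a2. Tox, on chromosome 4 from 6686353 to 6991557, fell by 3.09 ± 0.41 (SE; edgeR adjusted p = 0.0161), Rgs16 by 3.20 ± 0.57, Cd244 by 1.88 ± 0.31 and Cd160 by 1.69 ± 0.25, from 408 ± 55.0 to 127 ± 38.03 CPM. Lag3 fell by 2.11 ± 0.43, from 61.8 ± 31.0 to 14.3 ± 4.22 CPM (edgeR adjusted p = 0.0421). Pdcd1, which encodes PD-1, was at 1809.8 ± 539 CPM without and 775 ± 755 CPM with SMARTA (log2 fold change −1.22, edgeR adjusted p = 0.302), where replicate 3 with SMARTA had 1647 CPM and replicates 1 and 2 had 322 and 356. Without replicate 3 its log2 fold change was −2.44 and its edgeR adjusted p 0.0481. Havcr2, which encodes TIM-3, had a log2 fold change of −1.18 (edgeR adjusted p = 0.427) and Entpd1, which encodes CD39, −0.29 (edgeR adjusted p = 0.745), and neither passed. With 1 library left out Havcr2 ranged from −2.14 to −0.68 and was called in none of the 7 fits. The median over the list was −1.20 and camera found it lower (adjusted p = 9.22e-09), with adjusted p = 0.122 with an estimated correlation. No member was called without replicate 4 lacking SMARTA or without replicate 2 with SMARTA, 1, 6 and 4 without replicates 1, 2 and 3 lacking SMARTA, and 7 and 3 without replicates 1 and 3 with SMARTA.

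Progenitor and memory genes moved both ways. S1pr1, the receptor for exit from tissue along sphingosine phosphate, rose from 128 ± 40.8 to 715 ± 146 CPM (log2 fold change 2.49 ± 0.29, SE; edgeR adjusted p = 0.0119). The transcription factor Lef1 rose by 1.34 ± 0.22, and Myb fell by 2.34 ± 0.49. The other 17 of 20 tested members were not called, and adjusted over the list alone 5 rose and 4 fell. Of the 7 fits that leave out 1 library, S1pr1 lost its call only in that without replicate 4 lacking SMARTA. Lef1 was called only without replicate 2 lacking SMARTA or replicate 1 with SMARTA, and Myb only without the latter. Tcf7, which encodes TCF1, was at 109 ± 44.6 CPM without and 301 ± 155 CPM with SMARTA (1.47 ± 0.43; edgeR adjusted p = 0.106), and Il7r at 136 ± 91.4 and 653.5 ± 366 CPM (2.26 ± 0.53; edgeR adjusted p = 0.0578). Both genes were higher in 3 of 3 libraries with SMARTA than in the 4 others, and Slamf6 differed by −0.25 (edgeR adjusted p = 0.661). With 1 library left out Il7r passed only without replicate 2 lacking SMARTA or replicate 1 with SMARTA (edgeR adjusted p = 0.0305 and 0.0331). The list as a whole did not pass by camera (adjusted p = 0.239).

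Of 23 tested cytokine and chemokine genes 7 were called lower and 1 higher, 12 and 1 when adjusted over the list alone, and 14 had a negative and 9 a positive log2 fold change. Ccl4 fell from 2039.7 ± 831 to 234 ± 74.1 CPM (log2 fold change −3.12 ± 0.39, SE; edgeR adjusted p = 0.0141), Xcl1 from 282 ± 132 to 21.3 ± 6.67 CPM (−3.73 ± 0.48; edgeR adjusted p = 0.0155). Ccl3 fell from 883 ± 382 to 58.2 ± 33.9 CPM. Ifng, which encodes interferon gamma, was at 659.6 ± 318 CPM without and 85.6 ± 64.4 CPM with SMARTA (−2.95 ± 0.69), and Tnf at 119 ± 72.9 and 63.6 ± 26.6 CPM. Neither passed (edgeR adjusted p = 0.0587 and 0.391), though Ifng passed without replicate 2 lacking SMARTA or replicate 1 with SMARTA (0.0421 and 0.0467). The list's median was −1.77 and camera found it lower (adjusted p = 2.07e-09), with adjusted p = 0.17 with an estimated correlation. Myeloid cells also express Spp1, Ccl9 and Ccl3, and summed neutrophil markers were at 69.9 ± 35.3 CPM without and 17.5 ± 5.25 CPM with SMARTA. Macrophage and monocyte markers were at 293 ± 66.0 and 291 ± 74.1 CPM, of which Ctss made up 46.0% and 62.3%. The others of that list summed to 158 ± 49.9 CPM without SMARTA and to 246, 41.8 and 41.03 CPM in replicates 1, 2 and 3 with SMARTA. No member was called without replicate 4 lacking SMARTA or without replicate 2 or 3 with SMARTA; 4, 11 and 6 were called without replicates 1, 2 and 3 lacking SMARTA, and 9 without replicate 1 with SMARTA.

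Of the T cell receptor activation and immediate early genes, the transcription factors Irf8 (401 ± 241 to 47.5 ± 19.0 CPM) and Irf4 (178 ± 67.5 to 38.6 ± 19.0 CPM) and the signalling inhibitor Spry1 fell, with log2 fold changes of −3.08, −2.21 and −2.87. The other 26 of 29 tested members were not called, and 7 fell when adjusted over the list alone. By camera the list was lower (adjusted p = 0.0264), with adjusted p = 0.65 with an estimated correlation and 0.274 by fry. In the list of the T cell receptor complex and proximal signalling, the phosphatase-family gene Ubash3a rose by 0.90 ± 0.18 (SE). Of 25 tested members 20 had a positive log2 fold change, and 5 rose when adjusted over the list alone. Camera found this list higher (adjusted p = 0.00101), with adjusted p = 0.178 with an estimated correlation. Cd3e (0.15), Cd8a (−0.21) and Cd8b1 (0.65) were not called (edgeR adjusted p = 0.778, 0.715 and 0.111), and Cd3e changes sign under library totals. Among IL-2 receptor and STAT5 response genes only the amino acid transporter Slc7a5 was called, with a log2 fold change of −2.03. Adjusted over the list alone 3 rose and 2 fell, and the list did not pass (camera adjusted p = 0.818). With 1 library left out, T cell receptor complex genes were called only without replicate 1 with SMARTA, where 4 rose. T cell receptor activation genes were called in none of the fits without replicate 3 or 4 lacking SMARTA or replicate 2 or 3 with SMARTA, and IL-2 response genes in none without replicate 1 or 4 lacking SMARTA or replicate 2 or 3 with SMARTA.

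DNA replication and mitosis genes fell together. Of 30 tested replication genes 13 were called lower and none higher, 25 when adjusted over the list alone, and of 30 tested mitosis genes 8 were called lower and none higher, 24 when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell from 395 ± 124 to 67.3 ± 33.9 CPM (log2 fold change −2.55 ± 0.43, SE; edgeR adjusted p = 0.0257). The replicative helicase subunits Mcm5 and Mcm7 fell by 1.84 ± 0.33 and 1.51 ± 0.27. Gins1 fell by 2.58. Ube2c, which marks mitotic proteins for destruction, fell from 119 ± 45.3 to 12.1 ± 3.65 CPM (−3.30 ± 0.40; edgeR adjusted p = 0.0131). The mitotic kinase Plk1 fell by 2.76 ± 0.38, Cdc20 by 2.36 ± 0.39 and the centromere histone Cenpa by 1.94 ± 0.25. Mki67 was lower in 3 of 3 libraries with SMARTA than in the 4 others (51.0 ± 7.93 against 18.6 ± 14.3 CPM) but did not pass (edgeR adjusted p = 0.28). The summed CPM of the mitosis list was 3422 ± 773 without SMARTA and 242, 741 and 1072 in replicates 1, 2 and 3 with SMARTA. Camera found both lists lower (adjusted p = 1.69e-24 for replication and 4.56e-29 for mitosis), with adjusted p = 0.17 and 0.17 with an estimated correlation. Replication genes were called in none of the fits without replicate 1, 3 or 4 lacking SMARTA or replicate 2 or 3 with SMARTA, and mitosis genes in none without replicate 4 lacking SMARTA or replicate 2 with SMARTA. Without replicate 1 with SMARTA 15 and 19 were called.

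Genes of amino acid transport and of serine and folate metabolism fell in 5 of 20 tested members, with none called higher; adjusted over the list alone 8 fell and 1 rose. Shmt1 and Mthfd1, enzymes of folate metabolism, fell by 2.61 ± 0.30 (SE; 106 ± 31.8 to 17.3 ± 3.84 CPM) and 1.86 ± 0.26, Psat1, of serine synthesis, by 1.74 ± 0.27 and the arginine transporter Slc7a1 by 1.41 ± 0.29. Camera found the list lower (adjusted p = 5.65e-06), with adjusted p = 0.122 with an estimated correlation. None were called without replicate 4 lacking SMARTA or without replicate 2 with SMARTA. In the chromatin regulator list the DNA methyltransferase Dnmt3a (−1.21) and the histone methyltransferase Suv39h1 (−1.17) fell and Ezh1 (1.14) rose among 30 tested. In the fits that leave out 1 library Dnmt3a and Ezh1 were called only without replicate 2 lacking SMARTA or replicate 1 with SMARTA, and Suv39h1 only without the former. Adjusted over the list alone 3 fell and 1 rose, and the list did not pass (camera adjusted p = 0.0906).

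Tissue residency and TGF-beta response genes rose in 3 of 23 tested members with none lower, 9 when adjusted over the list alone, and 21 had a positive log2 fold change, with a median of 1.23. Itgae, the CD103 integrin chain that binds E-cadherin, lies on chromosome 11 from 73090583 to 73147446 and rose from 3.00 ± 0.845 to 27.0 ± 7.87 CPM (log2 fold change 3.17 ± 0.35, SE; edgeR adjusted p = 0.011). Cdh1, E-cadherin itself, rose from 10.9 ± 4.33 to 137 ± 54.3 CPM (3.65 ± 0.39; edgeR adjusted p = 0.011), and Qpct rose by 2.17 ± 0.31. Cxcr6, also of this list, was at 1969 ± 239 and 3468 ± 1074 CPM (0.82 ± 0.23; edgeR adjusted p = 0.0945). Of the 7 fits that leave out 1 library it was called only in that without replicate 1 with SMARTA (edgeR adjusted p = 0.0212). Camera found the list higher (adjusted p = 7.05e-10), with adjusted p = 0.104 with an estimated correlation. Between 2 and 5 members were called with each library left out.

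Chemotactic receptor genes changed in 5 of 17 tested members. Ccr4 (log2 fold change 3.41), Ccr2 (2.03 ± 0.42, SE; 385 ± 113 to 1578 ± 897 CPM), Cxcr3 (1.55 ± 0.27; 439.7 ± 108 to 1288 ± 437 CPM) and the leukotriene receptor Ltb4r1 rose. Ccr8 fell (−2.47 ± 0.42; 108 ± 19.9 to 19.5 ± 10.1 CPM). Adjusted over the list alone 11 rose and 2 fell. Camera found the list higher (adjusted p = 0.000101), with adjusted p = 0.13 with an estimated correlation. Among integrin and adhesion genes the selectin ligand Selplg (0.93 ± 0.18) and Itgb3 (1.85 ± 0.38) rose of 25 tested, and 5 rose and 1 fell when adjusted over the list alone. Camera found this list higher (adjusted p = 0.00248), with adjusted p = 0.178 with an estimated correlation. No chemotactic receptor gene was called without replicate 4 lacking SMARTA or replicate 3 with SMARTA, and integrin and adhesion genes were called only without replicate 2 lacking SMARTA or replicate 1 with SMARTA.

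Cytolytic granule genes did not pass as a list (camera adjusted p = 0.458), with 14 of 22 tested members negative and 8 positive. Gzmb, which encodes granzyme B, was at 3502 ± 581 CPM without and 3368 ± 2328 CPM with SMARTA (log2 fold change −0.06 ± 0.43, SE), and Prf1, perforin, at 795 ± 316 and 319.5 ± 99.6 CPM (−1.32 ± 0.35; edgeR adjusted p = 0.0794). The cathepsin Ctsw was the only 1 of 22 tested members called, higher by 0.81 ± 0.17 (edgeR adjusted p = 0.0424), and it was called in none of the 7 fits that leave out 1 library. Adjusted over the list alone 1 rose and 3 fell. Among terminal effector and NK receptor genes the transcriptional regulator Id2 (1.10 ± 0.18) and Ly6c2 (1.46 ± 0.25) rose and the fractalkine receptor Cx3cr1 fell, from 138 ± 24.8 to 24.4 ± 9.23 CPM (−2.49 ± 0.31; edgeR adjusted p = 0.0141). None of these 3 genes was called in the fits without replicate 4 lacking SMARTA or replicate 2 with SMARTA. Cx3cr1 was called in the other 5 fits, Id2 only without replicate 2 lacking SMARTA or replicate 1 with SMARTA, and Ly6c2 in these 2 and without replicate 3 lacking SMARTA. Klrg1 differed by −1.21 (edgeR adjusted p = 0.462), and by −1.78 to −0.26 with 1 library left out. Adjusted over the list alone 2 rose and 3 fell, and this list of 21 tested members did not pass (camera adjusted p = 0.818).

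Small shifts of whole lists with no called member passed camera but neither alternative list test. These lists were cholesterol biosynthesis (median log2 fold change −0.50, camera adjusted p = 0.00215), oxidative phosphorylation (−0.30, with 35 of 38 members negative, camera adjusted p = 0.00302) and ribosomal proteins (−0.19, camera adjusted p = 0.0121). Their values were adjusted p = 0.663, 0.65 and 0.752 with an estimated correlation, and 0.273, 0.146 and 0.273 by fry. Adjusted over the list alone 1, 0 and 0 members fell. Among the smallest p in these lists were those of Cyp51 (−1.57, edgeR adjusted p = 0.0519) and Tmem97 (−1.55) in the first, Cycs (−0.81) and Atp5a1 (−0.56) in the second, and Rpl5 (−0.77) in the third. Glycolysis (camera adjusted p = 0.217; Hk2 −0.95, Gapdh −0.62), endoplasmic reticulum stress (0.453; Asns −1.33, Ddit3 1.12), costimulatory receptors (0.81; Crtam −2.21, Cd70 −3.05) and heat shock (0.996; Hspd1 −1.001, Dnajb1 0.96) did not pass and had no called member. In the hypoxia list (camera adjusted p = 0.635) only Car12 was called, lower by −2.72, and in the apoptosis list (0.988) only Bcl2a1d, lower by −1.34. With 1 library left out, both were called only without replicate 2 lacking SMARTA. The mean and median of the costimulatory list (−0.05 and 0.19) and of the heat shock list (0.07 and −0.18) had opposite signs.

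**Figure D2:**
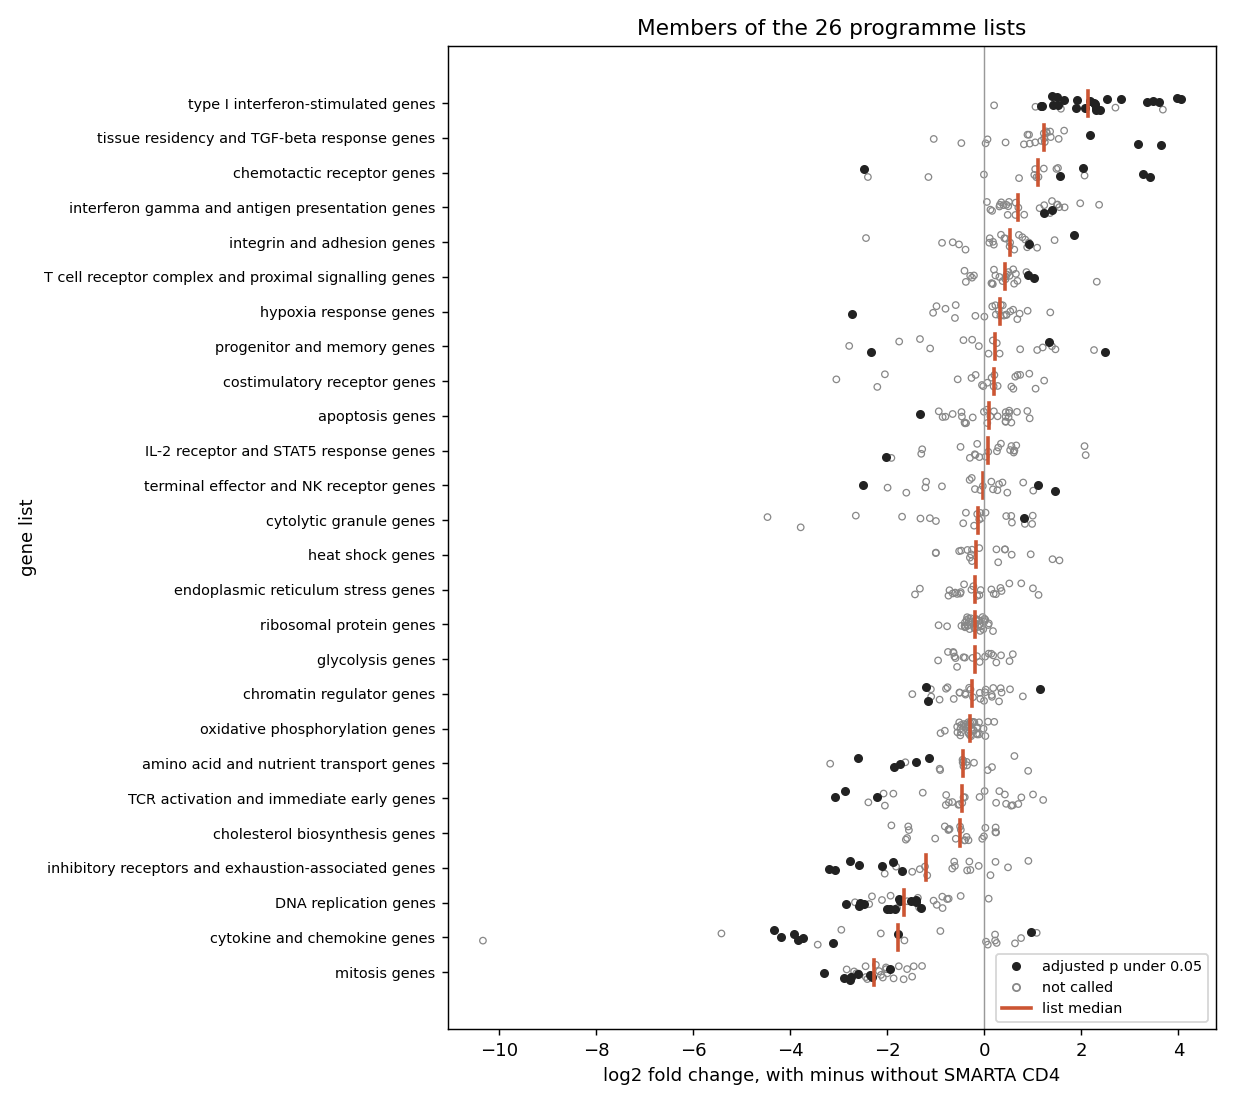
Log2 fold changes (with minus without SMARTA, x axis) of the tested members of the 26 programme lists (y axis, ordered by median), filled where edgeR adjusted p was under 0.05 and open otherwise, with each list's median as an orange bar; vertical scatter within a row has no meaning. The interferon-stimulated list has the highest median (2.13) and the mitosis list the lowest (−2.28).

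Sums of marker genes of other cell types were compared as an account of what the sort held. Summed CPM of macrophage and monocyte markers was 293 ± 66.0 without and 291 ± 74.1 with SMARTA, and of dendritic cell and MHC class II markers 465 ± 159.7 and 374 ± 293. B and plasma cell markers summed to 444 ± 97.1 and 439 ± 239 and those of CD4 and regulatory T cells to 853 ± 85.7 and 802 ± 181. Melanoma markers were at 71.1 ± 47.6 and 94.0 ± 33.7, fibroblast markers at 194 ± 23.9 and 209 ± 39.4 and keratinocyte markers at 18.0 ± 3.21 and 13.9 ± 4.68. The gene Cd4 itself was at 3.11 ± 2.49 and 4.40 ± 3.53 CPM. Neutrophil markers summed to 69.9 ± 35.3 without and 17.5 ± 5.25 with SMARTA (two-sided exact permutation p = 0.0571, adjusted over the 12 marker lists 0.343). Endothelial markers summed to 100.1 ± 14.8 and 169 ± 26.2 (exact permutation p = 0.0286, the smallest 35 splits allow, adjusted 0.343). Fewer than 7 lists at the smallest p cannot pass over 12 lists, so these adjusted values decide nothing. Single genes carried several of these sums, as a look at their largest gene after seeing the data shows. Pecam1 made up 92.4% of the endothelial sum without and 97.1% with SMARTA, and the other endothelial markers summed to 7.57 ± 3.71 and 4.96 ± 5.28 CPM. Gpnmb made up 46.1% and 88.8% of the melanoma sum. The other melanoma markers summed to 38.3 ± 33.2 without and 10.6 ± 1.43 CPM with SMARTA, where replicate 2 without SMARTA had 87.8, and 9 of 10 tested members had a negative log2 fold change, none of them called. Thy1 made up 88.3% of the fibroblast sum without SMARTA, Ighm 87.8% of the B cell sum and Il2rb 98.1% of the NK sum. Capg made up 74.7% and 67.4% of the CD4 and regulatory T cell sum, and the others of that list summed to 216 ± 73.9 and 261 ± 75.6 CPM. Sfn made up 60.7% and 84.3% of the keratinocyte sum, and the other keratinocyte markers summed to 7.08 ± 3.15 and 2.18 ± 0.886 CPM. Il1r2 made up 43.2% and 31.4% of the neutrophil sum, and the others summed to 39.8 ± 36.5 and 12.0 ± 6.04 CPM. NK cell markers, several of which CD8 T cells also express, were at 4142 ± 600.5 and 3443 ± 745 CPM. By camera the neutrophil (adjusted p = 0.00494), NK (0.0068) and mitochondrially encoded (0.0068) lists were lower, with adjusted p = 0.17, 0.178 and 0.65 with an estimated correlation. By fry the neutrophil and NK lists passed (adjusted p = 0.0397 each) and the mitochondrially encoded list did not (0.334). The decoy receptor Il1r2 of the neutrophil list was the only marker called (−2.29, edgeR adjusted p = 0.0169), and it lost its call without replicate 4 lacking SMARTA or replicate 2 with SMARTA. The other lists, with camera adjusted p from 0.171 to 0.996, did not pass.

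Single libraries stood apart in the markers and in the overall profile. Replicate 1 with SMARTA had 4818 summed CPM of erythroid and platelet markers, against 10.3 to 237 in the other 6 libraries, and replicate 2 without SMARTA had 12823 of mitochondrially encoded genes, against 1825 to 5392. Replicate 1 with SMARTA also had the highest sums of dendritic cell markers (707, against 262 and 154 in replicates 2 and 3) and of B cell markers (715, against 303 and 299). Its macrophage markers other than Ctss summed to 246 CPM, against 41.8 and 41.03 in replicates 2 and 3 and 158 ± 49.9 without SMARTA. For the erythroid list the mean log2 fold change (1.51) and the direction of the camera test (lower) had opposite signs. On the first principal component of the 500 most variable genes, which held 40.5% of the variance, replicate 1 with SMARTA lay at 70.5, replicates 2 and 3 with SMARTA at 14.4 and 10.8, and the 4 libraries without SMARTA between −35.4 and −7.96. Spearman correlations over these genes averaged 0.498 within the group without SMARTA, 0.264 within the group with SMARTA and 0.178 between the groups. With both libraries that stand apart left out, a choice made after seeing the data, 1257 genes were called, 611 higher and 646 lower. Among them were 29 interferon-stimulated, 21 replication, 27 mitosis, 8 exhaustion-associated and 6 tissue residency genes in the directions given above.

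**Figure D3:**
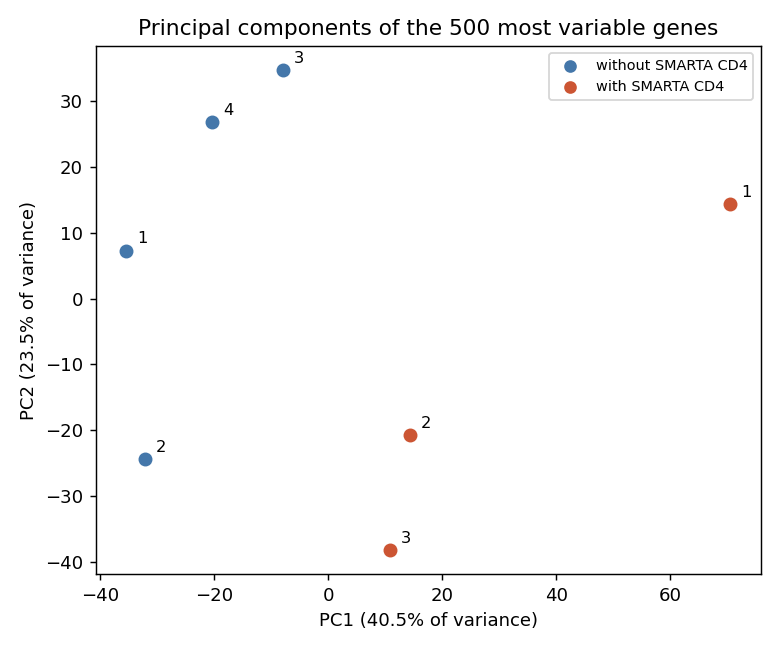
First (40.5% of variance) and second principal component of log2 CPM of the 500 most variable genes, without (blue, n = 4) and with SMARTA (orange, n = 3), labelled by replicate number. Replicate 1 with SMARTA lies at 70.5 on the first component and the next library at 14.4.

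**Figure D4:**
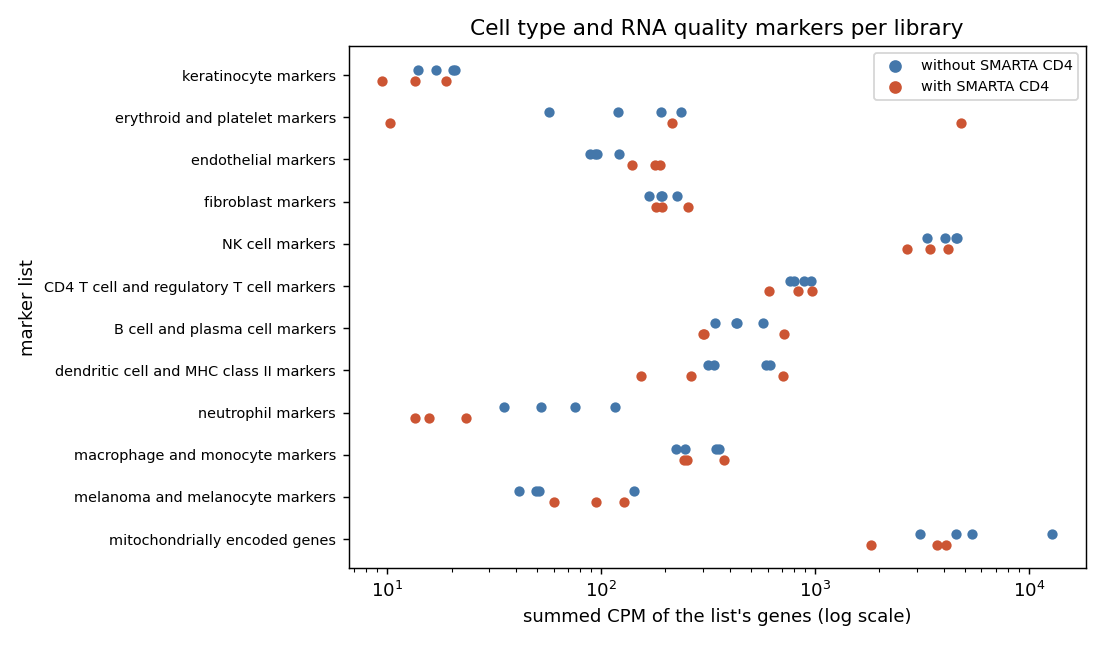
Summed CPM (log axis) of the 12 marker lists in each library, without (blue) and with SMARTA (orange). The erythroid and platelet list reaches 4818 CPM in replicate 1 with SMARTA, and the mitochondrially encoded list 12823 CPM in replicate 2 without SMARTA.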

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

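The tests of single libraries, of other leukocytes' RNA, of marker sums without their largest gene, of GC content and gene length and of the number of detected genes were chosen only after the results they bear on had been seen. The test of other splits was planned before the data were examined. Those of red cell RNA and of sequencing depth bear on a pattern seen in the data and were written before their own results only.

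Among 170 values tested in the 4 libraries without SMARTA, 7 had 1 library far from the other 3 by Dixon's ratio, where chance gives about 5%. Replicate 2 without SMARTA was apart in 5 of them: Mki67 was highest there at 5.97 log2 CPM (5.52 to 5.58 in the others), Gpnmb highest at 5.61 (4.61 to 4.71), Esam lowest at −3.92 (−0.06 to 0.72), the summed CPM of melanoma markers highest at 142 (41.1 to 51.3) and the number of genes with a count lowest at 20048 (21568 to 21730). Unlike Mki67, the summed CPM of the mitosis and replication lists was lowest in that library, though not flagged. It was 2345 (3489 to 4167 in the others) for mitosis and 4159 (5910 to 7587) for replication. Replicate 4 without SMARTA had the highest Synpo at 4.73 log2 CPM (3.94 to 4.06) and the lowest Id2 at 10.04 (10.29 to 10.33). Groups of 3 were not tested this way.

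The 500 calls were not reached by regrouping the libraries: of the 35 splits into 4 and 3, only the real 1 gave as many, and the highest of the others gave 0. If the libraries are independent samples, this argues against chance assignment to groups at a share under 0.05, though 35 splits allow none below 1 of 35. The labels do not say whether libraries of a group came from separate animals. The splits therefore cannot exclude that libraries of a group are alike for a reason other than SMARTA cells.

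Replicate 1 with SMARTA had the lowest summed CPM of interferon-stimulated genes in its group (4108, against 6902 and 7981 in replicates 2 and 3). Leaving it out could therefore hardly lower the list. The list's mean log2 fold change without it, 2.41 ± 0.19 (SE over members) against 2.18 with it, tests nothing. With each library left out in turn the mean lay between 1.93 and 2.41. A larger amount of other leukocytes' RNA would have to raise their markers by about as much as this list's summed CPM (log2 ratio 1.62). The highest log2 ratio among 6 such lists was −0.0097 (macrophages and monocytes, SE 0.26, with 18 of 20 listed genes tested). With each list's largest gene left out it was 0.28 (CD4 T cells). A steady amount of such RNA whose own interferon-stimulated genes rose would leave the markers unchanged, which these sums cannot exclude. With trends of GC content and gene length removed the mean was 2.19 ± 0.17. The marker sums argue against a larger amount of RNA of these 6 cell types as the whole cause, and the corrected mean against GC content or gene length. No list marks CD8 T cells other than OT1 cells, so the sums cannot decide about such cells. Trbv12-1, the beta segment of the OT1 receptor, held 96.3 ± 1.55% of beta variable segment counts without and 92.4 ± 2.38% with SMARTA. Which cells carried the other segments was not tested. An effect of SMARTA cells on interferon signals in the tumour may underlie the difference, as a hypothesis that these libraries do not test.

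The lower replication and mitosis genes were weighed on the mitosis list, whose mean log2 fold change was −2.25. Without replicate 1 with SMARTA, the library with the lowest sum, it was −1.85 ± 0.10 (SE over members), and with trends of GC content and length removed −2.27 ± 0.08, which argues against either as the whole cause. These SE, like those of the interferon-stimulated list, cover the spread over genes that vary together and not that between libraries. A smaller share of dividing cells among OT1 cells with SMARTA, or a lower level in each cell, may both give this pattern, and bulk libraries do not separate them.

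Replicate 1 with SMARTA lay apart on the first component by a gap of 53.0% of the range. Depth does not account for all of it: with all libraries thinned to the smallest total the gap was 52.6%. Without the erythroid and platelet genes it was 50.9%, but these were only 6 of the 500 genes. Their removal could hardly move the component and cannot exclude other red cell RNA. At that equal depth it had the fewest genes with a count, 19356 against at least 19881 in the others. It already had the fewest at its own depth, the largest of the 7, so thinning could not change its rank and this count decides nothing about fewer distinct molecules. A technical and a biological origin remain open.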

How the results depend on the processing

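The block by file number, library totals, omission of both libraries that stand apart, and the GC and length correction were chosen after seeing the data. With the other scalings, no filter, limma-voom, no robust estimation or a log2 fold change of at least 1, 449 to 575 genes were called. The count was 842 (491 lower) with CPM of at least 5 in at least 3 libraries, 1741 (822 higher, 919 lower) with DESeq2, which made 43 false calls in simulated data, 1537 (772 and 765) with limma-voom and sample quality weights, 7 (5 and 2) at an adjusted p under 0.01, 561 (398 lower) with library totals, 1257 (611 and 646) with both libraries that stand apart left out, and 1097 (597 and 500) with the GC and length correction. With the replicate number as a block edgeR called 0 genes (0 higher, 0 lower), with 1631 at an unadjusted p under 0.05 and every one of the 500 genes in the same direction. The file names number the libraries with SMARTA 2 to 4, where the titles have 1 to 3. With the file numbers as a block edgeR also called 0 genes (0 higher, 0 lower), with 1868 at an unadjusted p under 0.05. DESeq2 and limma-voom were not run with either block. Same-numbered libraries did not deviate together by title (correlations −0.14, 0.03 and −0.27) or by file name (−0.09, −0.06 and −0.04), and none correlated best with its own number in either, so neither numbering shows a pairing. With 1 library left out 17 to 907 genes were called, 10 to 510 higher and 7 to 397 lower, the fewest without replicate 4 lacking SMARTA and the most without replicate 1 with SMARTA. Fewer libraries leave fewer degrees of freedom. Lists called numbered 18 by camera, 0 with an estimated correlation, 13 by fry and 15 to 20 under the other settings. The difference in mean Spearman correlation within and between groups was 0.242 over the 500 most variable genes and 0.0213 over all tested. No called gene of the naming rule reversed. Reversed log2 fold changes, all of genes not called, were, with sample quality weights, Hbb-bt (−1.37) and Cd3e (−0.073); without replicate 1 with SMARTA, Hbb-bt (−0.11), Cd3e (−0.013), Cd4 (−0.43), Entpd1 (0.047) and Gzmb (0.31); without replicate 1 lacking SMARTA, Gzmb (0.03); without replicate 2 with SMARTA, Gzmb (0.02); with library totals, Cd3e (−0.0062); with both libraries left out, Hbb-bt (−0.39), Cd3e (−0.10) and Gzmb (0.30); and with the GC and length correction, Gzmb (0.16). At their other extreme with 1 library left out, Hbb-bt was at 4.46, Cd4 at 1.17, Entpd1 at −0.60 and Gzmb at −0.73. The erythroid list passed camera as higher without replicate 2 with SMARTA (adjusted p = 0.0247) and as lower without replicate 1 with SMARTA (0.0119), and its highest adjusted p with 1 library left out was 0.979. Medians of the IL-2 and apoptosis lists changed sign between scalings. The cause of other differences between settings was not tested.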

Other observations

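The gene families here were chosen after the table of all genes was seen, so their values describe the pattern they were picked for and test nothing. The look at T cell receptor segments was also chosen after the main results; the refit of the nucleolar family was written before its result.

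Of 6 tested Ifitm genes Ifitm1, Ifitm2 and Ifitm3, which encode antiviral membrane proteins, rose with SMARTA (log2 fold changes 2.25, 2.51 and 2.35; Ifitm3 from 48.3 ± 7.06 to 247 ± 78.6 CPM, edgeR adjusted p = 0.011). Of 7 tested Schlafen genes Slfn1, Slfn2 and Slfn5 rose (1.65, 0.99 and 2.16), and of 12 tested Parp genes Parp6, Parp10 and Parp12 rose (1.29, 1.38 and 2.17). All 8 tested Gimap genes, GTPases of lymphocytes, had positive log2 fold changes, and Gimap3 was called (1.11 ± 0.16, SE; 1550.0 ± 111 to 3351 ± 489 CPM).

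Genes with symbols in Nop, Nol or Noc, most of which encode nucleolar proteins, had a negative log2 fold change in 18 of 19 tested members, and Nolc1 (−1.32), Nop56 (−1.10), Nop16 (−1.28) and Noc2l (−1.37) were called. Nop56, a component of the particles that modify ribosomal RNA, fell from 417 ± 59.9 to 195 ± 19.1 CPM (edgeR adjusted p = 0.0252). Of 8 chaperonin genes Cct2 (−0.78) and Cct5 (−0.88) fell, and the metal-binding metallothioneins Mt1 (−1.72; 67.0 ± 10.5 to 20.4 ± 1.18 CPM) and Mt2 (−2.69) fell. Of 15 tubulin genes Tubb6, Tuba1b and Tubb5 fell, by 2.38, 1.53 and 1.11, and 3 had a positive log2 fold change. Without replicate 1 with SMARTA the mean log2 fold change of the nucleolar family was −0.78 ± 0.11 (SE over genes), against −0.70 with it. Because the family was picked for being lower in these same libraries, this refit cannot decide whether the decrease would hold in others.

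Trbv12-1, the beta segment of the OT1 receptor, held 96.3 ± 1.55% (SD, n = 4) of the counts over 35 beta variable segments without SMARTA and 92.4 ± 2.38% (n = 3) with SMARTA. Trbv13-1, the segment of the SMARTA receptor, had 0, 0, 2 and 0 counts in the libraries without and 0, 0 and 3 in those with SMARTA, of 3168 to 6395 beta segment counts per library, where 3 counts correspond to 0.0469% to 0.0947%. Of 43 tested alpha variable segments 37 had a positive log2 fold change with SMARTA, with a mean of 0.55 ± 0.11 (SE over segments); these are values only and claim no change. Which cells carried the other beta and alpha segments was not tested.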
